A study of Schizosaccharomyces pombe with 16 samples.

How the data were processed

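The deposited values are, per the file headers and the labels, 1 number per probe and array for 16 two-colour Agilent arrays, taken here as a log2 ratio of the mutant over WT. The sources give neither the base nor the direction of the deposited log2 ratio in words. Base 2 is likely, because the largest deposited value, 6.18, would be a 72.7-fold change in base 2 and 484.8-fold as a natural log, though this does not settle it. Mutant over WT is likely, because per the labels each title names the mutant and per the series record the strains were compared relative to WT. What the authors did to normalize the values is not given in the sources used here. The medians of the arrays lay between -0.0265 and 0.0267.

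Per the labels' protocols, cells grew in rich YES medium to mid-log phase, replicates were grown separately, and total RNA was reverse transcribed and labelled. Whether the WT RNA of different arrays came from 1 culture is not given in the sources used here. Per the labels, the mutant was in Cy5 on 7 arrays and in Cy3 on 9. The deposited values were already turned to 1 direction, since arrays of the same mutant with opposite dyes correlated across genes at r from 0.557 to 0.948 over 16 pairs, as did arrays with the same dyes (0.605 to 0.966, 9 pairs).

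From the deposited values, a gene value was computed as the mean of the exon probes of a gene, or of the probes of a non-coding RNA. The 15207 probes held 5097 for exons, 4885 for introns, 4697 for junctions of adjacent exons, 402 for junctions that skip an exon, and 126 for non-coding RNAs. Of 5195 genes, 28 had several such probes. Genes with values on at least 2 arrays of every group were tested, 5163 in all, 121 of them non-coding RNAs. 11445 probe values were missing. Names came from a reference table of 12645 genes on assembly ASM294v3, in which 5094 of 5195 IDs matched and 4238 had a symbol. That table was used only for names and for the order of genes along a chromosome. Most genes rest on 1 exon probe, and probe sequences were not given, so signal from near-identical copies cannot be told apart.

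limma (version 3.58.1, R 4.3.3) fitted 4 group means and a gene-wise dye term to all 16 arrays at once, with lmFit and eBayes. Each mutant mean was tested against 0, and 5 further contrasts compared S2A with S7A, S2A/S7A with S2A, S2A/S7A with S7A, S7E with S7A, and S2A/S7A with the sum of S2A and S7A (non-additivity). All tests were two-sided. Past the threshold means a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a contrast. The dye term passed for 2 genes, and 781 genes had an unadjusted p under 0.05, where 258 would by chance.

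Gene lists were tested against other genes with camera at a preset correlation of 0.01, for lists of at least 4 measured genes, adjusted over 27 lists within a contrast, and again with an estimated correlation. They hold 504 genes in all: P-cell and M-cell mating genes, mating and Ste11 targets, meiotic Mmi1 targets, phosphate genes, iron uptake, iron use, copper uptake, zinc genes, thiamine genes, nitrogen starvation, glucose-repressed genes, stress response, heat shock proteins, histones, MBF targets, septation, M-G1 genes, cytosolic ribosomal proteins, ribosome biogenesis, respiratory chain, proteasome, ergosterol synthesis, arginine and lysine synthesis, heterochromatin factors, genes for CTD kinases, phosphatases and elongation, Tf2 retrotransposons, wtf genes, flocculins, telomere-linked helicases and genotype markers. Some genes sit in 2 lists, for example inv1 in nitrogen starvation and glucose-repressed genes, and hsp16 in stress response and heat shock proteins. Subtelomeric genes are those with a midpoint within 100 kb of an end of chromosome I or II. For splicing, the mean of the exon probes was taken from each intron or junction probe, and the differences went through the same fit (4445 introns, 4429 junctions and 371 exon-skipping junctions).

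The tests, the lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined. Named genes are the 8 highest and 8 lowest in each mutant among those past the threshold with 1 sign on every array of that mutant, the 3 subtelomeric genes and the 3 members of each passing list with the smallest p, the 4 highest and 4 lowest in each contrast between mutants and among introns, and always rpb1, pho1, ste11, tlh1, tlh2 and the genotype markers. 1 gene that this rule picks is left out of the text. Other genes, such as those shared by all 4 mutants or named from lists that did not pass, were chosen after their values were seen. So were the mutants whose values are given for lists that passed in no mutant or were too small to test. Alternatives chosen after seeing the data were repeated values left out, 3 arrays that stand apart left out (S7A replicate 4, S2A replicate 4 and S7E replicate 1), lists tested on genes complete on all 16 arrays (4829), and subtelomeric genes taken by ID prefix. On every array but S7A replicate 4, 1 value recurs, for example on 75 probes of S7A replicate 3, and 150 genes hold such a value at least once. On S7A replicate 4 no value was on more than 4 probes. Scaling to equal spread divided centred arrays by their median absolute value, in place of limma's between-array scaling, which returned no numbers on these values.

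The fit was first run on simulated arrays with 200 changed genes. Of genes changed by log2 0.5 it recovered 96% in S7A, 96% in S2A, 95% in S2A/S7A and 87% in S7E, and of those changed by log2 1, 100%, 100%, 100% and 99%. For non-additivity it recovered 60% at log2 0.5 and 97% at log2 1. camera gave an unadjusted p under 0.05 to 4 of 200 unshifted lists. The simulated genes were drawn independently, so this does not check the preset correlation for genes that move together. The simulations with 1 shared WT RNA gave WT a spread equal to that of an array's residual, and the counts of shared genes in them were chosen after the values were seen.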

Results

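The series measured RNA from fission yeast (Schizosaccharomyces pombe) strains whose RNA polymerase II carried altered serines in the C-terminal domain (CTD), the tail of repeated heptads on Rpb1, the largest subunit. In S7A the seventh residue of each altered heptad was alanine, in S2A the second, in S2A/S7A both, and in S7E the seventh was glutamate. Per the labels, each strain carried 14 altered heptads behind 18 rump repeats. Splicing-sensitive Agilent arrays compared each mutant with wild type (WT) in the other colour, with 4 arrays for S7A, 4 for S2A, 5 for S2A/S7A and 3 for S7E. The number of arrays limits the precision. Of 15207 probes, between 13061 (S2A/S7A replicate 4) and 14918 (S7E replicate 1) had a value. Values are given as log2 of the mutant over WT, a direction and a base taken as likely since the sources state neither, with the standard error (SE), and ± is that SE unless SD is named. The title of the series names subtelomeric genes, so these form a comparison of their own.

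The CTD alleles were not checked on the array, since probe sequences were not given. RNA of rpb1 rose in S2A (0.73 ± 0.058, adjusted p = 6.66e-08) and in S2A/S7A (0.34 ± 0.052, adjusted p = 5.19e-05), and was 0.080 ± 0.058 in S7A (adjusted p = 0.313) and 0.041 ± 0.068 in S7E (adjusted p = 0.614). In S7E, the rise of rpb1 passed the test when all probes of the gene were averaged (adjusted p = 5.00e-04). Of the genes that often mark S. pombe strains, ade6 fell in S2A (-0.42 ± 0.079) and in S7E (-0.49 ± 0.092), and ura4 passed the test in none of the 4 mutants, with values from 0.15 in S2A/S7A to 0.60 in S7E. Its value in S7E passed without S7E replicate 2 (0.84, adjusted p = 0.0444) or 3 (0.93, 0.0217) and in a fit of the S7E arrays alone (0.89, 1.93e-13). In S7A and S2A/S7A it passed in a fit of the arrays of that mutant alone (0.22 and 0.21) and without S7A replicate 4, S2A replicate 4 and S7E replicate 1 (0.26 and 0.22). In S7E leu1 fell (-0.15 ± 0.054) and his7 rose (0.65 ± 0.23), but without S7E replicate 1 his7 was at -0.056 and neither passed, and leu1 also failed without S7E replicate 3 (adjusted p = 0.0794). Across genes, which are not independent replicates, arrays of the same mutant correlated at r from 0.557 to 0.966 and arrays of different mutants from 0.118 to 0.756.

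In S7A, ght5, the gene of a high-affinity glucose transporter, rose most, by 3.37 ± 0.14 (10.3-fold, n = 4 arrays), and str1, a siderophore-iron transporter gene, fell by 4.23 ± 0.22. The acid phosphatase gene pho1 rose by 2.37 ± 0.16 and the meiotic gene mei2 by 1.66 ± 0.21. Of the 10 iron uptake genes 6 fell and 1 rose. Genes changed in both directions, 928 higher and 857 lower of 5163 tested, and 110 and 84 of these by at least 1.5-fold.

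The 8 highest genes in S7A also held eaf6 (2.91 ± 0.13), which encodes a subunit of a histone acetyltransferase complex, SPAC27D7.11c (2.04 ± 0.12), SPBC19C7.04c (1.80 ± 0.11), SPBC1271.08c (1.74 ± 0.069) and tlh2 (1.69 ± 0.27). The rise of eaf6 rested on its exon probe, since its junction probe read 0.079. Among the 8 lowest, besides str1, were str3 (-2.71 ± 0.21), abc3 (-2.59 ± 0.21), fio1 (-2.49 ± 0.13), fip1 (-2.45 ± 0.15), mpn1 (-2.45 ± 0.064), frp1 (-2.23 ± 0.20) and SPAPB18E9.04c (-1.99 ± 0.14). fio1 and fip1 encode the oxidase and the permease of reductive iron uptake, frp1 a ferric reductase, abc3 a vacuolar transporter, and mpn1 an exonuclease acting on U6 RNA. Adjusted p (limma) for these 16 genes was at most 2.47e-04, the value for tlh2. On S7A replicate 4 the falls were smaller, with str1 at -3.31 (-4.68 to -4.46 on the other 3), str3 at -1.53 and fip1 at -1.70. The subtelomeric gene gdt1 fell by 1.80 ± 0.11, and SPAC186.02c rose by 0.75 ± 0.055.

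Of the 27 lists tested, 7 passed in S7A. In the iron uptake list, 1 gene rose and 6 fell with a median of -1.23 (2 and 7 adjusted over the list alone, camera adjusted p = 0.00229, adjusted p = 0.627 with an estimated correlation); str2 (0.18 ± 0.060) was the one that rose. Of the 9 glucose-repressed genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.414 with an estimated correlation), led by the transporter genes ght1 (1.48 ± 0.15) and ght3 (0.97 ± 0.10) and the invertase gene inv1 (0.60 ± 0.068). Among 20 mating and Ste11 targets, 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.821 with an estimated correlation), with mam2 at 0.79 ± 0.071 and the mating transcription factor gene ste11 at 0.69 ± 0.078. Of 11 MBF targets, genes of the G1 to S phase transition, 5 fell and 0 rose (0 and 7 adjusted over the list alone, camera adjusted p = 0.0330, adjusted p = 0.821 with an estimated correlation), among them cdc22 (-0.40), yox1 (-0.23) and rad21 (-0.22). The 140 cytosolic ribosomal protein genes had 13 lower and 1 higher (0 and 5 adjusted over the list alone, camera adjusted p = 0.0463, adjusted p = 0.821 with an estimated correlation), with rps1802 (-0.52), rpl2502 (-0.47) and rpl1601 (-0.38) among them. Of 48 respiratory chain genes 12 fell and 6 rose (6 and 13 adjusted over the list alone, camera adjusted p = 0.0463, adjusted p = 0.821 with an estimated correlation), with atp5 (-0.46), cox4 (-0.45) and atp3 (-0.37) lower. The 13 Tf2 retrotransposons had a median of 0.29, and limma called 0 of them (4 higher at an unadjusted p under 0.05, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0463, adjusted p = 0.821 with an estimated correlation). Tf2-12 stood at 0.32, Tf2-7 at 0.31 and Tf2-10 at 0.30. The Tf2 median was -0.47 on replicate 4, against 0.50, 0.37 and 0.77 on replicates 1 to 3. Without replicate 4 these 3 copies passed, at 0.59, 0.52 and 0.49 (adjusted p at most 0.00394), as they did with scaled arrays and with array weights.

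The call on Tf2 ended without S7A replicate 1 (adjusted p = 0.235), 2 (0.0580) or 3 (0.348) and with a replicate block (0.153), while those on MBF targets (0.117) and mating genes (0.0660) ended without replicate 4. Ribosomal protein genes missed the threshold without replicate 2 (adjusted p = 0.143) or 4 (0.354), respiratory genes without replicate 1 (0.0523), 2 (0.0580) or 4 (0.112). With arrays centred on their median, Tf2, ribosomal protein and respiratory genes missed it as well (adjusted p = 0.0528, 0.0575 and 0.0575). So did they without the dye term (0.0512, 0.0565 and 0.0512). Without S7A replicate 4, S2A replicate 4 and S7E replicate 1, mating genes (0.0816), MBF targets (0.106), ribosomal protein (0.149) and respiratory genes (0.0738) missed it. Respiratory genes also missed it with scaled arrays (0.0544), and ribosomal protein genes on genes with a value on all 16 arrays (0.0542). Among single genes, rad21 missed the threshold without replicate 1, 2 or 3 (adjusted p up to 0.0852), cdc22 without replicate 4 (0.0592) and rpl2502 without replicate 2 (0.0549). rad21 also missed it when all probes of the gene were averaged (adjusted p = 0.105). A limit on every count against WT is that the test against 0 leaves out the spread of WT itself: had all WT channels held 1 RNA, simulated unchanged genes gave a median of 1107 calls in S7A. The S7A count rose to 2692 with arrays scaled to equal spread and to 3073 with array weights.

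In S2A, the largest rise was in mug62, by 5.74 ± 0.18 (n = 4 arrays), followed by the cytidine deaminase gene cdd1 (4.11 ± 0.073) and the small heat shock gene hsp16 (3.61 ± 0.15). The uracil-regulatable genes urg1 (-3.36 ± 0.16) and urg2 (-3.07 ± 0.15) fell most. The M mating-type gene mat1-Mc fell by 2.49 ± 0.098, and the M-factor gene mfm2 fell by 2.56 ± 0.14 on its exon probe, while its intron probe read -0.11. In all 1613 genes were higher and 1398 lower of 5163, and 338 and 256 by at least 1.5-fold. All 8 septation genes fell and 13 of 14 stress genes rose.

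The other genes among the 8 highest were the telomere-linked helicase genes tlh1 (2.98 ± 0.16) and tlh2 (2.97 ± 0.27), SPAC27D7.09c (2.68 ± 0.21), SPAC27D7.10c (2.68 ± 0.21) and SPBCPT2R1.09c (2.65 ± 0.17). The others among the 8 lowest were alr2 (-2.89 ± 0.37), mat3-Mc (-2.61 ± 0.11), SPAC1039.01 (-2.44 ± 0.10) and isp5 (-2.41 ± 0.21). Probes for tlh1 and tlh2, for mat1-Mc and mat3-Mc and for Tf2 copies may read near-identical sequences, so values within such a family are uncertain as separate genes. The rises of mug62 and cdd1 rested on exon probes: 3 junction probes of cdd1 had a mean of 0.12 (smallest unadjusted p of the 3 = 0.00298), and the intron probes of mug62 a mean of 0.0091. mug62 had no junction probe to compare. S2A replicate 4 stood apart for 10 of these 16 genes, for example mug62 at 4.70 (5.96 to 6.18 on the other 3), alr2 at -1.21 (-3.58 to -3.30) and SPAC27D7.09c at 1.38 (3.04 to 3.21). ftm1 (2.36 ± 0.10), ftm4 (2.27 ± 0.098) and prt2 (1.52 ± 0.064) were the subtelomeric genes with the smallest p. In S2A, ste11 fell by 1.12 ± 0.078 and pho1 rose by 0.76 ± 0.16.

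Of the 27 lists, 9 passed in S2A. Of 14 stress genes 13 rose with a median of 0.83 (13 and 0 adjusted over the list alone, camera adjusted p = 2.96e-04, adjusted p = 0.431 with an estimated correlation), among them gst2 (1.42 ± 0.12) and fbp1 (0.58 ± 0.068). Among heat shock proteins, 7 of 14 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.431 with an estimated correlation), with wos2 at 0.78 and hsp10 at 0.60. All 8 septation genes fell (0 and 8 adjusted over the list alone, camera adjusted p = 0.00154, adjusted p = 0.601 with an estimated correlation), with the endo-glucanase gene eng1 at -1.14 ± 0.13, adg1 at -0.83 ± 0.087 and agn1 at -0.64 ± 0.069. Of 140 ribosomal protein genes 79 fell and 0 rose (0 and 79 adjusted over the list alone, camera adjusted p = 2.09e-08, adjusted p = 0.606 with an estimated correlation), with rpp202 at -1.32 ± 0.17, rps2602 at -0.60 and rps403 at -0.44. The junction probe of rpp202 fell less, at -0.35. Ribosomal protein medians were -0.50, -0.33 and -0.34 on S2A replicates 1 to 3 and 0.035 on replicate 4, where 21 of the 140 genes held the repeated value of that array. With repeated values left out the median on replicate 4 was 0.029, and the list passed (camera adjusted p = 9.01e-10). Of 36 ribosome biogenesis genes 23 fell and 2 rose (2 and 24 adjusted over the list alone, camera adjusted p = 1.30e-05, adjusted p = 0.431 with an estimated correlation), with utp13 (-0.53), nop9 (-0.51) and gar1 (-0.47) lower. Of 48 respiratory chain genes 33 fell and 8 rose (8 and 33 adjusted over the list alone, camera adjusted p = 2.82e-06, adjusted p = 0.431 with an estimated correlation), with cox4 (-1.09), cyt1 (-1.03) and atp5 (-0.96) lower. All 13 Tf2 retrotransposons rose with a median of 0.69 (13 and 0 adjusted over the list alone, camera adjusted p = 0.00147, adjusted p = 0.606 with an estimated correlation), among them Tf2-10 (0.79), Tf2-6 (0.74) and Tf2-7 (0.69). Of 25 wtf genes, a family that holds meiotic drivers, 13 rose (13 and 0 adjusted over the list alone, camera adjusted p = 0.00772, adjusted p = 0.606 with an estimated correlation), with wtf11 (0.72), wtf20 (0.39) and wtf12 (0.35) among them. Of 8 meiotic Mmi1 targets 6 rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.0341, adjusted p = 0.431 with an estimated correlation), with ssm4 (1.14), crs1 (0.59) and mei4 (0.33) among them, and this call ended without S2A replicate 4 (adjusted p = 0.135) and without S7A replicate 4, S2A replicate 4 and S7E replicate 1 (0.124). Simulated unchanged genes with 1 shared WT RNA gave a median of 1094.5 calls in S2A.

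In S2A/S7A, cmt2 rose most (3.24 ± 0.097, n = 5 arrays), followed by eaf6 (3.09 ± 0.11) and the heme uptake gene shu1 (2.77 ± 0.17). ght5 rose by 2.76 ± 0.13 and pho1 by 1.75 ± 0.14. SPBC36.02c fell most (-2.15 ± 0.14), followed by urg2 (-1.93 ± 0.13) and urg1 (-1.92 ± 0.15). All 13 Tf2 retrotransposons rose, with a median of 1.82. In total 1813 genes were higher and 1434 lower of 5163, and 324 and 246 by at least 1.5-fold.

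Also among the 8 highest were SPBPB21E7.08 (2.73 ± 0.083), tlh1 (2.70 ± 0.15), tlh2 (2.62 ± 0.24) and aes1 (2.59 ± 0.099). Also among the 8 lowest were alr2 (-1.77 ± 0.33), put4 (-1.75 ± 0.090), SPBC1683.04 (-1.73 ± 0.17), SPAC11D3.10 (-1.68 ± 0.091) and isp5 (-1.65 ± 0.19); put4 encodes a proline permease and stood at -1.47 on replicate 3 (-1.91 to -1.79 on the other 4). The junction probe of eaf6 read -0.14. The subtelomeric gene SPBPB2B2.18 rose by 2.59 ± 0.082. ste11 rose by 0.20 ± 0.071, a call that ended without replicate 1 (adjusted p = 0.109) or 2 (0.0638), with centred arrays (0.0588) and with scaled arrays (0.0710).

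Of the 27 lists, 12 passed in S2A/S7A. For the 13 Tf2 copies (13 and 0 adjusted over the list alone, camera adjusted p = 1.82e-07, adjusted p = 0.524 with an estimated correlation), Tf2-6 (1.86), Tf2-7 (1.81) and Tf2-10 (1.80) had the smallest p. Of 25 wtf genes 18 rose (18 and 0 adjusted over the list alone, camera adjusted p = 0.00811, adjusted p = 0.608 with an estimated correlation), with wtf11 (1.04), wtf20 (0.38) and wtf12 (0.34) among them. Of 10 iron uptake genes 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0174, adjusted p = 0.544 with an estimated correlation), among them fio1 (1.27 ± 0.12) and sib1 (0.99 ± 0.048), which encodes a siderophore synthetase. Of 7 iron use genes 5 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.0428, adjusted p = 0.524 with an estimated correlation), with aco1 (0.69), isa1 (0.46) and pcl1 (0.39) among them. Of 8 Mmi1 targets 7 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.0174, adjusted p = 0.524 with an estimated correlation), with ssm4 (1.11), crs1 (0.62) and mei4 (0.46) among them and crs1 at 0.21 on replicate 3. Of 8 nitrogen starvation genes 6 fell and 1 rose (1 and 6 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.580 with an estimated correlation), with isp7 (-1.33) and fnx1 (-0.91) lower and inv1 (1.17) higher. All 8 septation genes fell (0 and 8 adjusted over the list alone, camera adjusted p = 2.02e-04, adjusted p = 0.524 with an estimated correlation), with eng1 (-1.27), agn1 (-0.96) and adg1 (-0.88) having the smallest p. Of 11 MBF targets 8 fell and 2 rose (2 and 8 adjusted over the list alone, camera adjusted p = 0.0372, adjusted p = 0.624 with an estimated correlation), with the cyclin gene cig2 at -1.01 ± 0.071, mik1 at -0.78 and tos4 at -0.53. Both lists fell less on replicates 1 and 2, with MBF medians of -0.11 and -0.23 against -0.74, -0.68 and -0.65 on replicates 3 to 5, and septation medians of -0.506 and -0.487 against -1.005, -0.930 and -0.947. M-G1 medians were -0.0047 and -0.089 against -0.39, -0.53 and -0.41.

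Ribosomal protein genes in S2A/S7A had 62 of 140 lower and 0 higher (0 and 55 adjusted over the list alone, camera adjusted p = 8.61e-07, adjusted p = 0.608 with an estimated correlation), with rpp1 (-0.60), rpl902 (-0.43) and rps402 (-0.40) lower. Ribosome biogenesis had 17 of 36 lower and 1 higher (1 and 17 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.608 with an estimated correlation), with nop9 (-0.39), gar1 (-0.36) and utp25 (-0.35) lower. The respiratory chain had 29 of 48 lower and 7 higher (7 and 30 adjusted over the list alone, camera adjusted p = 2.18e-04, adjusted p = 0.524 with an estimated correlation), with cyt1 (-0.80), cox4 (-0.75) and atp5 (-0.71) lower. Of 19 proteasome genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.0428, adjusted p = 0.608 with an estimated correlation), with rpn7 (0.38), rpt5 (0.34) and rpt3 (0.27) higher. Calls in S2A/S7A that ended with 1 array left out were those of the proteasome without replicate 1 (adjusted p = 0.0605) or 2 (0.134), of iron use without replicate 2 (0.0551) or 5 (0.0516) and of MBF targets without replicate 4 (0.0533) or 5 (0.0557). With arrays scaled to equal spread, nitrogen starvation (adjusted p = 0.0678) and proteasome genes (0.0536) missed the threshold. With 1 shared WT RNA, simulated unchanged genes gave a median of 1388.5 calls.

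In S7E, ght5 rose by 4.17 ± 0.17 (18.0-fold, n = 3 arrays), and all 9 glucose-repressed genes rose, with the invertase gene inv1 at 2.01 ± 0.080 and the alpha-glucosidase gene agl1 at 1.81 ± 0.092. mei2 rose by 2.30 ± 0.25. SPBPB10D8.01 fell by 3.04 ± 0.14, and str1 (-3.01 ± 0.26) and the carbonic anhydrase gene nce103 (-2.51 ± 0.14) fell as well. All 8 septation genes were lower. Counts were 1729 higher and 1425 lower of 5163, and 487 and 345 by at least 1.5-fold.

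Also among the 8 highest in S7E were SPBC19C7.04c (2.64 ± 0.13), cmt2 (2.48 ± 0.13), SPBPB21E7.08 (2.16 ± 0.11), psu2 (1.99 ± 0.13) and pbi2 (1.95 ± 0.14). Also among the 8 lowest were SPCC569.05c (-2.65 ± 0.15), dal52 (-2.62 ± 0.15), abc3 (-2.52 ± 0.25), hsp3104 (-2.04 ± 0.091) and pmp20 (-2.03 ± 0.21). pho1, high in S7A, was at 0.29 ± 0.18 in S7E (adjusted p = 0.187) and passed in a fit of the S7E arrays alone (adjusted p = 2.24e-06). ste11 rose by 0.50 ± 0.091, tlh1 by 1.72 ± 0.19 and tlh2 by 1.70 ± 0.32.

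Of the 27 lists, 11 passed in S7E. The glucose-repressed list had a median of 0.83 (9 and 0 adjusted over the list alone, camera adjusted p = 7.84e-05, adjusted p = 0.0977 with an estimated correlation), and the transporter gene ght6 rose by 1.34 ± 0.13. For the 8 septation genes (0 and 8 adjusted over the list alone, camera adjusted p = 5.58e-05, adjusted p = 0.487 with an estimated correlation), eng1 (-1.83 ± 0.15), adg1 (-1.32 ± 0.10) and agn1 (-1.22 ± 0.081) had the smallest p. Of 10 M-G1 genes 7 fell and 1 rose (1 and 7 adjusted over the list alone, camera adjusted p = 0.00834, adjusted p = 0.519 with an estimated correlation), with the kinesin gene klp5 at -1.44 ± 0.11 and mcm2 at -0.74. Of 25 wtf genes 21 rose (21 and 0 adjusted over the list alone, camera adjusted p = 6.19e-07, adjusted p = 0.487 with an estimated correlation), with wtf20 (0.72), wtf12 (0.68) and wtf5 (0.58) among them, and all 13 Tf2 copies rose with a median of 1.20 (13 and 0 adjusted over the list alone, camera adjusted p = 2.84e-05, adjusted p = 0.519 with an estimated correlation), with Tf2-10 (1.26), Tf2-7 (1.23) and Tf2-13 (1.22) among them. Of 10 histone genes 8 rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.00796, adjusted p = 0.487 with an estimated correlation), with hta2 (0.62), hhf1 (0.49) and hhf3 (0.42) among them. On S7E replicates 2 and 3, 5 and 4 of the 10 histone genes held the repeated value of the array. With repeated values left out the list passed (camera adjusted p = 0.0196). Of 20 mating genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.0462, adjusted p = 0.708 with an estimated correlation), with map1 (0.68) and ste7 (0.68) higher.

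Of 8 Mmi1 targets 5 rose in S7E (6 and 0 adjusted over the list alone, camera adjusted p = 0.0481, adjusted p = 0.487 with an estimated correlation), with spo5 (0.58), mei4 (0.56) and ssm4 (0.47) among them. Of 7 thiamine genes 5 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.0361, adjusted p = 0.519 with an estimated correlation), with thi9 (-1.16), thi5 (-0.63) and thi4 (-0.34) among them. Of 36 ribosome biogenesis genes 28 fell and 1 rose (1 and 28 adjusted over the list alone, camera adjusted p = 6.84e-08, adjusted p = 0.426 with an estimated correlation), with utp25 (-0.91), utp21 (-0.77) and utp4 (-0.70) lower. Of 140 ribosomal protein genes 70 fell and 11 rose (11 and 67 adjusted over the list alone, camera adjusted p = 5.05e-05, adjusted p = 0.732 with an estimated correlation), with rpl902 (-0.88), rpl2701 (-0.86) and rps403 (-0.62) lower. The fall of rpl2701 rested on its exon probe, since its junction probe read -0.064. The call on mating genes ended without S7E replicate 2 (adjusted p = 0.0848) or 3 (0.107), and that on Mmi1 targets without replicate 2 (0.0588) and without S7A replicate 4, S2A replicate 4 and S7E replicate 1 (0.129). Thiamine genes missed the threshold when only genes with a value on all 16 arrays were tested (adjusted p = 0.0639). With 1 shared WT RNA, simulated unchanged genes gave a median of 713.5 calls in S7E.

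Across the 4 mutants, camera with an estimated correlation called 0 of the 27 lists in any mutant, with 2 lists per mutant at an unadjusted p under 0.05, and 0 in each of the 5 contrasts between mutants, so every list call rests on the preset correlation of 0.01.

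**Figure D1:**
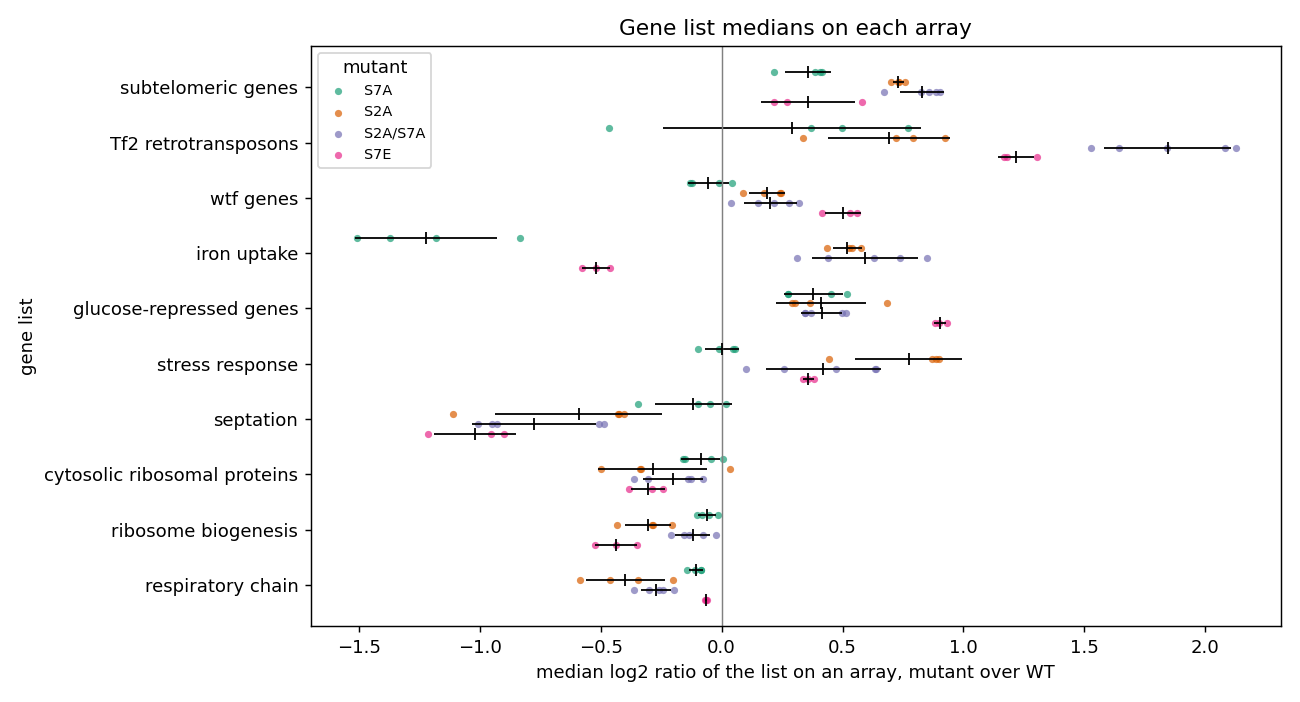
Median log2 of mutant over WT of 10 gene lists (y axis) on each array (dots), by mutant, with the mean and SD over arrays. Tf2 medians sat highest in S2A/S7A, at 1.82 in the fit, against 0.29 in S7A.

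Lists that passed in no mutant had small medians or members in both directions. In S2A the 9 M-cell genes had 2 higher and 3 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.267), with mat1-Mi at -0.91 and mam2 at 0.77. The 4 measured genes of the list drawn up for P cells had 2 higher and 1 lower in S2A (2 and 1 adjusted over the list alone, camera adjusted p = 0.561). Whether each member of that list is particular to P cells was not checked. Of 19 ergosterol genes in S7E 6 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.561), with erg31 at 1.02. Of 15 arginine and lysine synthesis genes in S2A/S7A 8 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.134). Of 17 heterochromatin factors in S2A 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.306), with rdp1 at 0.38 in S2A and -0.82 in S7A. Of the 16 genes for CTD kinases, phosphatases and elongation, 8 rose and 2 fell in S2A/S7A (8 and 2 adjusted over the list alone, camera adjusted p = 0.449). The 9 flocculins moved apart, with pfl9 higher and pfl7 lower in all 4 mutants, at 1.40 and -1.23 in S2A/S7A (3 and 2 adjusted over the list alone, camera adjusted p = 0.690). The 4 genotype markers tested gave 1 higher and 2 lower in S7E (2 and 2 adjusted over the list alone, camera adjusted p = 0.786). Lists of under 4 genes were not tested. All 3 phosphate genes rose in S7A, with pho84 at 1.01 ± 0.10 and tgp1 at 0.87 ± 0.080 (3 and 0 adjusted over the list alone). Of 3 copper genes ctr4 (-1.15 ± 0.18) and ctr5 (-0.74 ± 0.14) fell in S2A/S7A (0 and 2 adjusted over the list alone). Copper medians were -0.93 to -0.61 on the S2A/S7A arrays, but also -0.63 on S7A replicate 4 and -0.66 on S2A replicate 4. On replicates 1 to 3 they were 0.20 to 0.35 in S7A and 0.28 to 0.46 in S2A. A low copper median was thus not particular to the double mutant. Of 3 zinc genes in S2A, zrt1 fell by 1.30 ± 0.11 and zym1 rose by 0.73 ± 0.079 (1 and 1 adjusted over the list alone). In S7E zrt1 fell by 1.91 ± 0.12, adh4 also fell, and zym1 rose by more than in S2A.

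The mutants shared many calls. In all 4, 314 genes rose and 253 fell, against 34.1 and 17.8 from independent lists and 162.5 and 166 in simulations of unchanged genes with 1 shared WT RNA. By at least 1.5-fold, 43 rose in all 4 (0.0426 from independent lists, and a median of 7.5 in those simulations), among them ght5, inv1, tlh1, tlh2, pfl9, aes1 and gal10, and 14 fell (0.0133 and 6), among them isp4, isp5, put4, abc3, pfl7 and aat1. isp4 was at -1.67 ± 0.14 in S7A and -1.52 ± 0.17 in S7E. S2A and S2A/S7A shared 201 higher and 145 lower genes by at least 1.5-fold, against 21.2 and 12.2 from independent lists and medians of 16.5 and 14 in the simulations, and S7A and S2A shared 67 and 24, against 7.20 and 4.17 and against 16 and 14.5. In single simulations up to 16 genes fell in all 4 and up to 27 fell in both S7A and S2A, more than the 14 and 24 found. Part of the excess may come from WT channels, since the sources do not say whether the WT RNA of different arrays was shared.

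**Figure D2:**
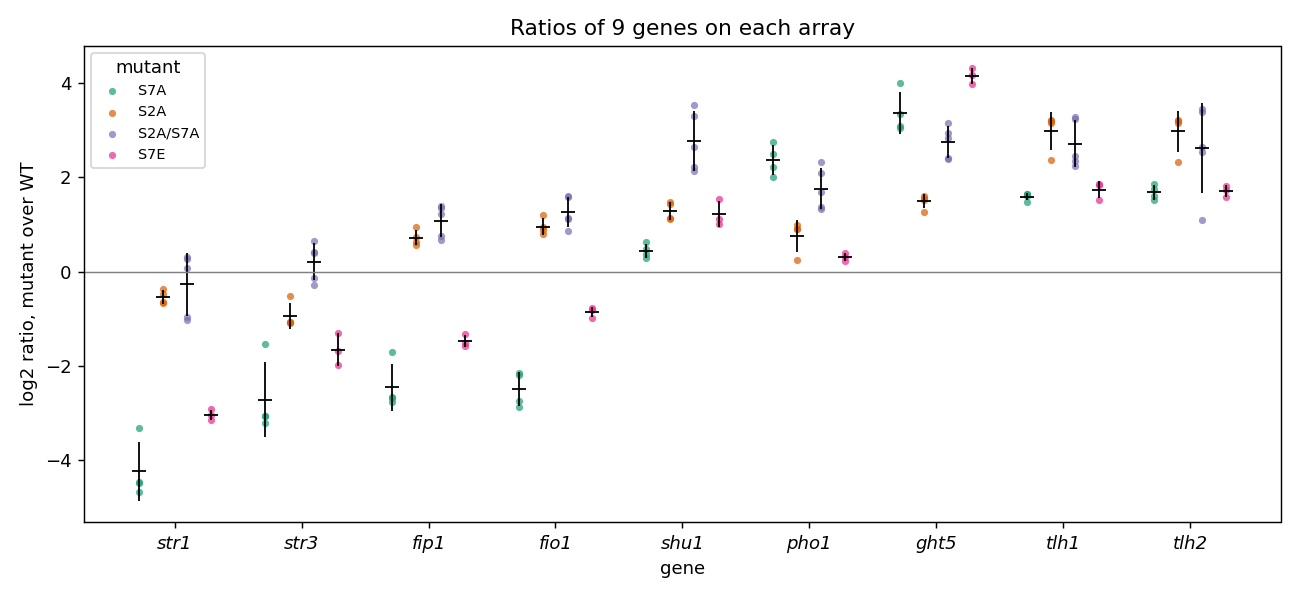
Log2 of mutant over WT (y axis) of 9 genes on each array (dots), by mutant, with the mean and SD over arrays. ght5 sat above 0 in all 4 mutants, at 3.37 in S7A and 4.17 in S7E, while str1 fell to -4.23 in S7A.

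Subtelomeric genes, the subject named by the title, rose more often than they fell. Of 122 tested genes within 100 kb of the ends of chromosomes I and II, 62 rose and 15 fell in S7A (66 and 15 adjusted over the list alone), 83 and 25 in S2A (84 and 25), 91 and 18 in S2A/S7A (94 and 18), and 65 and 29 in S7E (66 and 30). Medians were 0.38 in S7A, 0.75 in S2A, 0.82 in S2A/S7A and 0.39 in S7E. tlh1 and tlh2, which lie at chromosome ends, rose in all 4 mutants, from 1.59 (tlh1 in S7A) to 2.98 (tlh1 in S2A), each adjusted over the list of both alone as well. Against other genes, camera gave p = 1.13e-09 in S7A (p = 0.0362 with an estimated correlation), 7.39e-09 in S2A (p = 0.0448), 8.91e-13 in S2A/S7A (p = 0.0173) and 0.00343 in S7E (p = 0.277). The S7E call therefore ended with an estimated correlation, and it also ended when chromosome III ends were included (p = 0.439). The 20 genes nearest each end, 78 of which were tested, had medians per array of 0.51 ± 0.14 (SD, n = 4) in S7A, 0.99 ± 0.092 (SD, n = 4) in S2A, 1.12 ± 0.16 (SD, n = 5) in S2A/S7A and 0.58 ± 0.17 (SD, n = 3) in S7E, above 0 on all 16 arrays. Genes 21 to 50 from the ends had medians per array of -0.035 ± 0.038 (SD, n = 4) in S7A, -0.14 ± 0.074 (SD, n = 4) in S2A, 0.0027 ± 0.043 (SD, n = 5) in S2A/S7A and -0.21 ± 0.030 (SD, n = 3) in S7E. These 2 bands were chosen after the values were seen.

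**Figure D3:**
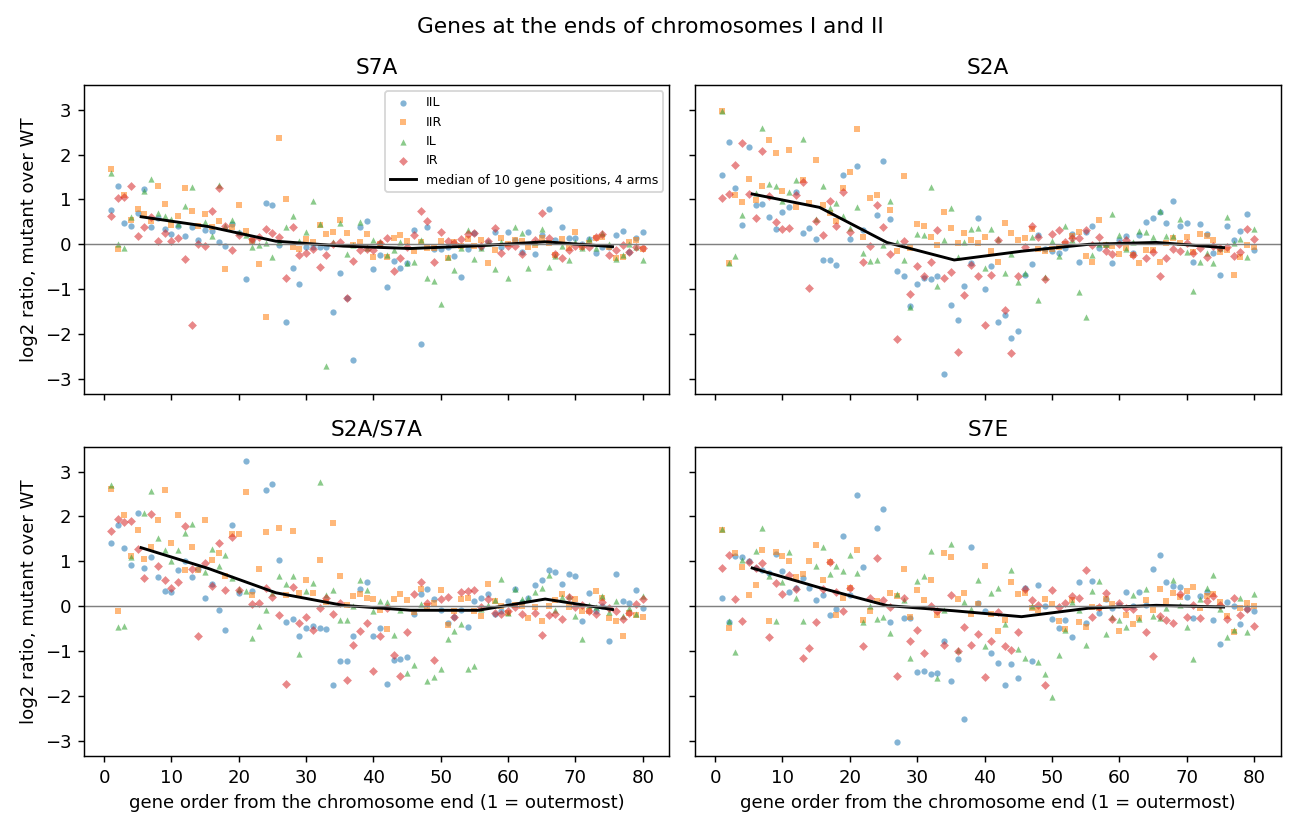
Log2 of mutant over WT (y axis) of genes by their order from the ends of chromosomes I and II (x axis, gene 1 nearest the end), 1 panel per mutant, with the black line the median per 10 positions over 4 arms. The line lies highest near the ends, where the outer 20 genes per arm had medians of 0.47 in S7A, 0.96 in S2A, 1.10 in S2A/S7A and 0.66 in S7E.

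Comparing S2A with S7A asks whether the 2 serines matter differently, though anything else that differs between the strains enters as well. Higher in S2A were mug62 (5.42 ± 0.26), cdd1 (3.81 ± 0.10), str1 (3.70 ± 0.32) and mpn1 (3.56 ± 0.090). Lower were mfm2 (-3.08 ± 0.20), mat3-Mc (-2.92 ± 0.15), eaf6 (-2.88 ± 0.18) and mat1-Mc (-2.78 ± 0.14). In limma's test of the difference, 1131 genes were higher in S2A and 1036 lower. 9 lists passed: 9 of 10 iron uptake genes were higher with a median of 1.41 (9 and 0 adjusted over the list alone, camera adjusted p = 1.01e-05, adjusted p = 0.401 with an estimated correlation), and 12 of 14 stress genes were higher (12 and 0 adjusted over the list alone, camera adjusted p = 1.67e-04, adjusted p = 0.482 with an estimated correlation). Subtelomeric genes were higher in S2A, with 53 of 122 past the test and 25 lower (57 and 25 adjusted over the list alone, camera p = 0.00280, p = 0.267 with an estimated correlation).

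Comparing S2A/S7A with S2A asks what the S7A change adds, but it cannot separate that change from anything else that differs between these strains. The double mutant had more RNA of mat3-Mc (3.14 ± 0.15), eaf6 (3.06 ± 0.17), mat1-Mc (3.06 ± 0.13) and mfm2 (2.96 ± 0.19), and less of mug62 (-5.52 ± 0.25), cdd1 (-4.12 ± 0.10), SPBC2A9.13 (-2.37 ± 0.25) and SPAC27D7.09c (-2.20 ± 0.28). Genes past the test were 622 higher and 583 lower, and the total of 1205 became 2210 with array weights and 2132 without S7A replicate 4, S2A replicate 4 and S7E replicate 1. 7 lists passed: all 13 Tf2 copies were higher in S2A/S7A with a median of 1.13 (13 and 0 adjusted over the list alone, camera adjusted p = 1.66e-09, adjusted p = 0.519 with an estimated correlation), and 5 of 14 stress genes were lower (0 and 5 adjusted over the list alone, camera adjusted p = 7.72e-04, adjusted p = 0.519 with an estimated correlation). Subtelomeric genes had 32 higher and 7 lower (39 and 8 adjusted over the list alone, camera p = 2.23e-04, p = 0.177 with an estimated correlation).

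Comparing S2A/S7A with S7A asks what the S2A change adds, with the same limit that other differences between the strains enter. cmt2 (4.01 ± 0.14), str1 (3.99 ± 0.30), fio1 (3.76 ± 0.17) and fip1 (3.54 ± 0.21) were higher in the double mutant, and SPAC11D3.17 (-1.74 ± 0.13), ctr4 (-1.64 ± 0.26), SPBC36.02c (-1.52 ± 0.21) and SPCC61.05 (-1.44 ± 0.11) were lower. The copper list, which holds ctr4, had a median of -0.63 on S7A replicate 4 and of 0.20 to 0.35 on S7A replicates 1 to 3. Counts were 1174 higher and 972 lower. 8 lists passed: 9 of 10 iron uptake genes were higher with a median of 2.41 (9 and 0 adjusted over the list alone, camera adjusted p = 8.29e-07, adjusted p = 0.285 with an estimated correlation), all 13 Tf2 copies were higher (13 and 0 adjusted over the list alone, camera adjusted p = 4.15e-08, adjusted p = 0.719 with an estimated correlation), and 7 of 8 septation genes were lower (0 and 7 adjusted over the list alone, camera adjusted p = 6.70e-04, adjusted p = 0.719 with an estimated correlation). Subtelomeric genes had 63 higher and 17 lower (64 and 17 adjusted over the list alone, camera p = 6.91e-07, p = 0.0781 with an estimated correlation).

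Comparing S7E with S7A sets a charged residue against alanine at Ser7, again along with any other difference between the strains. S7E exceeded S7A in cmt2 (3.24 ± 0.16), agl1 (2.13 ± 0.12), psu2 (2.03 ± 0.18) and atg43 (1.91 ± 0.11), and lay below it in eaf6 (-2.82 ± 0.20), dal52 (-2.36 ± 0.20), SPCC1529.01 (-2.15 ± 0.14) and SPCC569.05c (-2.09 ± 0.20). Counts were 1175 higher and 1043 lower. 10 lists passed: 23 of 25 wtf genes were higher in S7E (23 and 0 adjusted over the list alone, camera adjusted p = 2.23e-10, adjusted p = 0.345 with an estimated correlation), 21 of 36 ribosome biogenesis genes were lower and 1 higher (1 and 21 adjusted over the list alone, camera adjusted p = 9.09e-07, adjusted p = 0.345 with an estimated correlation), and 7 of 8 septation genes were lower (0 and 8 adjusted over the list alone, camera adjusted p = 1.29e-04, adjusted p = 0.491 with an estimated correlation). Subtelomeric genes had 30 higher and 34 lower (31 and 34 adjusted over the list alone, camera p = 0.513, p = 0.803 with an estimated correlation).

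Non-additivity asks whether S2A/S7A differs from the sum of S2A and S7A. str1 (4.52 ± 0.37), str3 (3.89 ± 0.36), SPBC23G7.10c (2.98 ± 0.19) and frp1 (2.93 ± 0.34) lay above the sum, and mug62 (-5.84 ± 0.31), cdd1 (-4.41 ± 0.13), SPBC2A9.13 (-2.62 ± 0.31) and SPAC27D7.11c (-2.51 ± 0.19) below it. 702 genes lay above and 661 below. 8 lists passed: all 13 Tf2 copies lay above (13 and 0 adjusted over the list alone, camera adjusted p = 1.58e-04, adjusted p = 0.644 with an estimated correlation), and 6 of 10 iron uptake genes lay above and 1 below (6 and 1 adjusted over the list alone, camera adjusted p = 0.00141, adjusted p = 0.633 with an estimated correlation). Subtelomeric genes had 26 above and 35 below (29 and 39 adjusted over the list alone, camera p = 0.0422, p = 0.444 with an estimated correlation). This contrast counts WT in a way the others between mutants do not, and unchanged genes with 1 shared WT RNA gave a median of 98 calls. The total of 1363 became 2453 with array weights and 2099 without S7A replicate 4, S2A replicate 4 and S7E replicate 1.

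Introns were compared with the exons of their gene. In S7A the exon level of eaf6 exceeded that of its intron, at -2.83 ± 0.13, and that of ppm1 (-2.06 ± 0.097), edc3 (-1.72 ± 0.085) and cdc3 (-1.67 ± 0.091), while intron signal was higher in dre4 (intron 2, 0.95 ± 0.11), lsd90 (intron 1, 0.92 ± 0.10, and intron 2, 0.89 ± 0.12) and pot1 (0.84 ± 0.11). In S2A, introns of tom20 (3.11 ± 0.22), tcg1 (3.10 ± 0.12), SPAC8C9.20 (2.63 ± 0.16) and mfm2 (2.34 ± 0.16) were higher, and those of mug62 (-5.73 ± 0.18), cdd1 (-4.16 ± 0.13), SPBC2A9.13 (-2.20 ± 0.15) and rad57 (-1.25 ± 0.072) lower. In S2A/S7A, introns of atp14 (1.85 ± 0.12), pet801 (1.33 ± 0.14), sei1 (1.28 ± 0.12) and SPCC1020.07 (1.20 ± 0.066) were higher, and those of eaf6 (-2.99 ± 0.12), nmd5 (-1.97 ± 0.094), osh2 (-1.28 ± 0.12) and rdh54 (-1.21 ± 0.15) lower. In S7E, introns of nar1 (2.07 ± 0.26), trm402 (1.67 ± 0.41), klf1 (1.63 ± 0.13) and SPAC22E12.15 (1.61 ± 0.46) were higher, and those of nmd5 (-1.62 ± 0.12), orc3 (-1.43 ± 0.47), mhf1 (-1.41 ± 0.44) and pps1 (-1.40 ± 0.095) lower. Adjusted p (limma) of these introns was at most 0.0253, the value for orc3. These values are differences, and several rested on the exon rather than the intron. Exon values were 2.91 for eaf6 in S7A, and 5.74 for mug62, 4.11 for cdd1 and -2.56 for mfm2 in S2A. They were -1.34 for sei1 in S2A/S7A, and -1.58 for klf1, 1.11 for orc3 and 1.62 for mhf1 in S7E. The differences of orc3, mhf1, trm402 and SPAC22E12.15 in S7E had SEs of 0.41 to 0.47, larger than those of all other introns named. For others the exon moved less, for example tom20 (-0.31) in S2A, ppm1 (-0.10) in S7A and nmd5 (0.17) in S2A/S7A.

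Of 4445 introns, 300 were higher and 1344 lower in S7A, 887 and 850 in S2A, 730 and 1494 in S2A/S7A, and 813 and 1144 in S7E. The median intron lay at -0.11 in S7A and -0.087 in S2A/S7A, a shift that centring removes. The S7A split became 716 higher and 851 lower with centred arrays and 936 and 1029 with scaled arrays, and the S2A/S7A split 1098 and 1077 with centred arrays and 1068 and 1052 with scaled arrays. In S7E the total of 1957 introns was 1230 without replicate 1, and in S7A the total of 1644 became 2579 with array weights. Of the introns lower than their exons, 1005 of 1344 in S7A, 352 of 850 in S2A, 889 of 1494 in S2A/S7A and 566 of 1144 in S7E also passed below 0 by their own ratio to WT, and of the higher ones 82 of 300, 336 of 887, 234 of 730 and 277 of 813 passed above 0. Of 4429 junctions 519 were higher and 89 lower than their exons in S7A, 288 and 354 in S2A, 337 and 226 in S2A/S7A, and 239 and 208 in S7E, and the S7E total of 447 was 176 without replicate 1. Of 371 exon-skipping junctions, 152 were higher and 3 lower in S7A, 34 and 18 in S2A, 60 and 20 in S2A/S7A, and 125 and 24 in S7E. The S7A skipping total of 155 fell to 26 with centred arrays, and the S7E total of 149 to 62 without replicate 1. Junction totals also hung on single arrays in S7A (608, and 362, 341 and 388 without replicates 1, 2 and 3) and S2A (642, and 366 without replicate 3). Skipping totals did so in S7A (94 without replicate 2), S2A (52, and 29 without replicate 3) and S2A/S7A (80, and 49 without replicate 1 or 3). With array weights, junction totals rose to 1659 in S7A and 1045 in S2A, and skipping totals to 284 in S7A, 130 in S2A and 167 in S2A/S7A. Without S7A replicate 4, S2A replicate 4 and S7E replicate 1, junction totals were 913 in S7A and 1070 in S2A/S7A (563 with all arrays), and skipping totals 261 in S7A, 124 in S2A, 189 in S2A/S7A and 90 in S7E. Without the dye term the S7E junction and skipping totals were 279 and 84, and with scaled arrays skipping totals were 97 in S2A and 82 in S7E. Of 4080 pairs of an intron and its junction, the intron was higher and the junction lower in 2 in S7A, 54 in S2A, 45 in S2A/S7A and 45 in S7E, and the reverse held in 180, 58, 140 and 63. Both were higher in 54, 61, 52 and 45, and both lower in 27, 116, 85 and 63. Since both differences take off the same exon mean, these counts decide nothing about splicing.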

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

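Of 186 values checked in groups of 4 or 5 arrays, 29 had 1 array far from the others, where chance alone gives about 1 in 20 (9.30), and 20 of the 29 lay on S2A replicate 4. No explanation for these arrays was tested, and leaving out S7A replicate 4, S2A replicate 4 and S7E replicate 1 together was chosen only after the values were seen. Each of those left out had the mutant in Cy5, as did S7A replicate 1 and S2A replicate 1, which were kept. S7E replicate 1 was the only S7E array with the mutant in Cy5, so array and dye cannot be told apart there. It correlated at 0.581 and 0.557 with S7E replicates 2 and 3, which correlated at 0.951 with each other.

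On S2A replicate 4, many large changes were smaller than on the other 3 arrays. mug62 stood at 4.70 (5.96 to 6.18 on the others), tlh1 at 2.37, tlh2 at 2.32, SPAC27D7.09c at 1.38, SPAC27D7.10c at 1.36, gst2 at 0.82, pho1 at 0.26 (0.90 to 0.98) and the stress list at a median of 0.44 (0.87 to 0.90). Among lower genes urg1 stood at -3.06, alr2 at -1.21 (-3.58 to -3.30), mat3-Mc at -2.07, mat1-Mc at -2.04, SPAC1039.01 at -2.16 and cyt1 at -0.73. Other changes were larger on that array: septation genes had a median of -1.11 (-0.43 to -0.40), with eng1 at -1.64, adg1 at -1.34 and agn1 at -0.97, and nop9 stood at -0.70 and rpb1 at 0.83. Without this array S2A/S7A against S2A gave 1577 genes, and non-additivity 1822.

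On S7A replicate 4 the iron genes str1 (-3.31, with -4.68 to -4.46 on the others), str3 (-1.53, -3.20 to -3.06) and fip1 (-1.70, -2.76 to -2.66) fell less, the mating list had a median of 0.53 (0.13 to 0.15), and subtelomeric genes one of 0.22 (0.39 to 0.42). eaf6 stood at 3.31 on S7A replicate 1 and SPBC1271.08c at 1.92 on S7A replicate 2. On S2A/S7A replicate 3 put4 stood at -1.47 and crs1 at 0.21 (0.74 to 0.76).

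Iron uptake genes differed between mutants: they lay higher in S2A/S7A than in S7A by a median of 2.41 (9 of 10 genes, camera adjusted p = 8.29e-07 over the lists, adjusted p = 0.285 with an estimated correlation). fio1 fell by 2.49 in S7A and rose by 1.27 in S2A/S7A. No technical or biological explanation was tested for this list.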

How the results depend on the processing

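Repeated values left out, 3 arrays left out together (S7A replicate 4, S2A replicate 4, S7E replicate 1), lists on genes complete on all arrays and subtelomeric genes by ID prefix were chosen after seeing the data. Of the values recomputed for counts and list tests, 303 stayed on the same side or within 1.5 times, 8 were larger or gained a call, 11 were smaller or lost one and 0 changed direction, and of those for named genes, named lists and junctions the numbers were 4542, 43, 113 and 2. With array weights the count became 3073 in S7A, 3300 for S2A against S7A, 2210 for S2A/S7A against S2A, 2453 for non-additivity and 2579 for S7A introns. These weights were 0.126 for S2A replicate 4, 0.157 for S7E replicate 1 and 0.306 for S7A replicate 4. Without those 3 arrays S2A/S7A against S2A gave 2132 genes and non-additivity 2099, and scaling to equal spread gave 2692 in S7A. The cause was not tested. With an estimated correlation camera passed 0 lists in S7A, S2A, S2A/S7A and S7E, with 2 in each at an unadjusted p under 0.05, and S7A kept 4 of 7 lists without the dye term and 4 with centred arrays. In S7E subtelomeric genes exceeded others by 0.354 with an estimated correlation (p = 0.277), by 0.0977 with chromosome III ends (p = 0.439) and by 0.126 by ID prefix (p = 0.725), and p over the 14 alternatives ranged from 4.98e-06 to 0.725. In S7A, S2A and S2A/S7A the excess was 0.159, 0.302 and 0.335 with chromosome III ends and 0.111, 0.240 and 0.322 by ID prefix, against 0.380, 0.725 and 0.779 with neither, and the test passed each time. These 2 alternatives take in other genes. his7 in S7E reversed to -0.0556 without S7E replicate 1, where leaving out other arrays gave up to 0.929, and to -0.0242 without the 3 arrays. Leaving out 1 array in turn gave 1191 to 1565 genes in S7A, 2584 to 3054 in S2A, 2921 to 3088 in S2A/S7A, 2490 to 2742 in S7E, 1815 to 2403 for S2A against S7A, 855 to 1577 for S2A/S7A against S2A, 1771 to 2035 for S2A/S7A against S7A, 1844 to 2073 for S7E against S7A and 981 to 1822 for non-additivity. Lists past the test ranged from 4 to 6 in S7A, 8 to 9 in S2A, 10 to 12 in S2A/S7A and 9 to 11 in S7E. Introns ranged from 1190 to 1638 in S7A, 1276 to 1645 in S2A, 1837 to 2039 in S2A/S7A and 1230 to 1611 in S7E, the last against 1957 with all arrays and lowest without S7E replicate 1. Leaving out 1 array lowered most counts, but without S2A replicate 4 those for S2A against S7A (2167 with all arrays), S2A/S7A against S2A (1205), non-additivity (1363) and S2A (3011) rose to the highest values given. The cause was not tested. The subtelomeric excess ranged from 0.305 to 0.432 in S7A, 0.685 to 0.700 in S2A, 0.747 to 0.821 in S2A/S7A and 0.289 to 0.369 in S7E. Signal over background was not given, so what it limits cannot be said.

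Deviations of arrays from their mutant's mean correlated at a median r of 0.085 over 21 pairs with the same replicate number (-0.223 to 0.409, 9 above 0.1) and of -0.0015 over 74 pairs with different numbers (-0.513 to 0.446, 26 above 0.1). For number 4 all 3 pairs exceeded 0.1, for number 2 it was 4 of 6, and for numbers 1 and 3 it was 1 of 6 each, while 4 of 16 arrays correlated best with their own number. Whether a replicate number marks a batch stays open. With a replicate block the counts were 1527 in S7A, 2746 in S2A, 3219 in S2A/S7A, 2776 in S7E, 2109 for S2A against S7A, 1074 for S2A/S7A against S2A, 2021 for S2A/S7A against S7A, 2067 for S7E against S7A and 1053 for non-additivity. The block ended the S7A call on Tf2 (adjusted p = 0.153) and that on his7 in S7E (0.101), and lowered the S7E junction total from 447 to 222 and skipping totals to 33 in S2A, 52 in S2A/S7A and 64 in S7E. The cause was not tested.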

Other observations

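The kinds of non-coding RNA, the bands of genes by order from a chromosome end, every test of an explanation below and every split of the arrays were chosen after the values were seen.

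All 25 mitochondrial tRNAs rose in S2A/S7A and in S7E, with medians per array of 0.88 ± 0.10 (SD, n = 5) and 0.89 ± 0.11 (SD, n = 3), while in S7A and S2A these medians were -0.049 ± 0.11 (SD, n = 4) and -0.024 ± 0.10 (SD, n = 4). Of 65 nuclear tRNAs 51 rose in S7E and 32 in S2A/S7A, against 16 in S7A and 12 in S2A. Of 28 snoRNAs 9 fell and 2 rose in S7A, 11 and 3 in S2A, 12 and 4 in S2A/S7A, and 3 and 10 in S7E. In S7A snoZ5 stood at -1.19, snoR38 at -1.04 and snoZ4 at -0.90. In all, 91 of 121 non-coding RNAs passed the test in S7E, 76 in S2A/S7A, 40 in S2A and 33 in S7A.

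The outer 20 genes of each arm rose in all 4 mutants, on each of 16 arrays. A dye bias is argued against, since the lowest mean of the array medians for 1 dye orientation was 0.449, above 0. A single WT RNA as the whole cause is argued against as well, since the medians of S2A/S7A and S7A differed by 0.61 (exact permutation test, two-sided, p = 0.00794, the smallest that 126 splits can give). These were the mutants with the highest and lowest of the 4 means (1.12 and 0.51), and the test was not adjusted for that choice. A part shared through WT stays open, as does the CTD change itself, which may raise these genes in each mutant.

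Introns called against their gene may reflect intron probes that follow their gene poorly. Over genes with a 2-fold exon change the median ratio of intron to exon log2 was 0.867 in S7A (5 genes), 0.39 in S2A (34), 0.54 in S2A/S7A (28) and 0.24 in S7E (35). That explanation needs a ratio under 0.5 in at least 3 mutants, and 2 were under it, so it stays open. S7A, with few genes, was not alone in missing it, since S2A/S7A did as well. Less spliced RNA would raise an intron against its exons, so by definition it does not describe the introns lower than their exons. Those were at least 48.1% of the called introns in each mutant in the main fit and with centred or scaled arrays. That share decides nothing about less splicing, because centring itself brings higher and lower calls near balance. For the introns higher than their exons less spliced RNA stays open. A count of pairs of an intron and its junction against the product of their shares was tried for it and dropped after its value was seen, because both differences take off the same exon mean.

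Exon probes of eaf6 and cdd1 rose by far more than their junction and intron probes, and that of mug62 by far more than its intron probes. mug62 had no junction probe to compare, so the test of junction probes does not cover it. Its intron probes say little, since the median ratio of intron to exon log2 in S2A was 0.39. Junction probes that do not respond on these arrays are argued against, since the lowest of the 4 median ratios of junction to exon log2 was 0.830, from 5 genes in S7A, and the others were 0.98 in S2A (32 genes), 1.08 in S2A/S7A (27) and 0.87 in S7E (34). That holds for junction probes in general and was not shown for each. In S7E 8 of the 34 genes had a ratio under 0.25. For all of these but sof1 (exon -1.01 ± 0.069) the exon SE was between 0.35 and 0.45. Such ratios cannot tell a junction probe that does not respond from an uncertain exon value. The S7A allele may lie behind eaf6, whose exon probe was at 0.034 in S2A and 0.0961 in S7E while it rose in S7A and S2A/S7A, but that does not separate the allele from anything else those strains share. An exon probe that reads other RNA stays open and was not tested.

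Other groupings of the arrays were counted on 4829 genes. For S2A against S7A (35 splits, 2022 genes, 99 at most in any other), S2A/S7A against S2A (100 drawn, 1154 and 440), S2A/S7A against S7A (100 drawn, 2027 and 1114) and S7E against S7A (35 splits, 2105 and 875), 1 split, the real one, gave as many genes. Each share is under 0.05 and argues against chance. It does not exclude chance, since 35 or 100 splits allow no smaller share. For non-additivity 5 of 100 drawn splits gave as many genes (1294, and 2310 at most in another), but mixed labels carry the differences between S2A, S7A and S2A/S7A into that contrast, so these splits decide nothing about it. Sign flips against WT were too few for a share under 0.05: 8 in S7A (1641 genes, 40 at most in another), 8 in S2A (2825 and 931), 16 in S2A/S7A (3045 and 18) and 4 in S7E (2951 and 46).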
